A study of Mus musculus with 140 samples.

How the data were processed

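RNA from gastrocnemius muscle was measured in male C57B6/J mice aged 10 to 11 weeks. Total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced as paired reads of 100 bp. The labels list 140 samples, and 137 of them have a file. The 3 samples without one are replicates 3 and 4 of the mice exercised in the rest phase and taken at 0 h, and replicate 3 of their sedentary controls.

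The submitters' processing notes name FastQC 0.11.5, Trim Galore 0.4.3, cutadapt 1.16, STAR 2.5.3a, featureCounts 1.5.2 and edgeR 3.2.23, and the mm10 (GRCm38) genome build. The annotation release, the strand setting and the filter that left 11461 genes are not given in the sources used here. Each deposited file holds one signal value per gene, made by the authors as reads per M (mega) of a scaled library size. The values of a library sum to between 0.633 M and 1.90 M, so they are not plain counts on that scale. In each library every value was a whole multiple of the worth of 1 read within a tolerance of 0.05 read, so the reads could be recovered. The recovered totals ran from 2.19 M to 27.6 M reads per library, with a median of 11.0 M. Over all libraries the median gene had a mean value of 12.0, and the lowest gene 1.16. Gene identifiers were matched to symbols and positions in the GENCODE annotation of GRCm38, and 11449 of 11461 had a match.

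The values were analysed as log2(value + 0.5) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation. A single model held the 24 groups formed by phase, treatment and hour, so that all contrasts shared 1 estimate of the spread of each gene. Exercise was compared with sham at each hour in each phase (12 contrasts). The difference between the phases was tested as an interaction at each hour and jointly over the 6 hours. Sham mice of both arms were compared at equal clock times by an F test over 6 clock times. Rhythms were tested with a cosine and a sine of 24 h period in each of 4 series, and the change of rhythm with exercise as the difference of these terms. P values were adjusted by the Benjamini-Hochberg method within each contrast, and an adjusted p under 0.05 counted as a pass. The plan had been the edgeR quasi-likelihood test on counts. Because the deposited values are not counts, limma on the log scale took its place, and edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. No gene was removed beyond the deposited list.

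The design, the repeats listed below as planned, 28 gene lists and the rule for named genes were set before the data were examined. The rule took genes with an adjusted p under 0.05 and a mean log2 value of at least 1. It left out predicted Gm and Rik genes and mitochondrial, ribosomal, small nucleolar and microRNA genes. It then took the 10 largest rises and the 10 largest falls at 0 h and 4 h, the 5 and 5 at other hours, and the 5 smallest p values for each rhythm. Members of the gene lists could also be named as examples. The lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, and adjusted over the 336 list tests of exercise and separately over the 168 list tests of the interaction.

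For each library a transcript-length slope was computed over 10801 protein-coding genes, as the slope of its log2 deviation from the mean of all libraries on the log2 exon length of the genes. It ran from -0.29 to 0.41 per doubling of length. The first component of the variation within groups held 51.9% of the within-group variance and correlated with this slope (r = 0.84 over 137 libraries; no p was computed). The third component, with 4.82%, had a higher mean in replicates 5 and 6 (0.079, SD 0.075) than in replicates 1 and 2 (-0.058) and 3 and 4 (-0.025). The SD over replicates 1 to 4 was 0.055. The labels give no batch, so the slope and replicate strata (1 and 2, 3 and 4, 5 and 6) were used as stand-ins. The comparisons were repeated, as planned, with size factors by relative log expression, DESeq2, the replicate number as a block, replicate strata, a slow-fibre covariate, a fit of each contrast with its own libraries alone, leaving out 1 library at a time, an F test for rhythm, an estimated correlation and fry. Added after the data had been seen were edgeR on recovered reads, pseudocounts of 0.1 and 2 (the latter planned for the clock genes), a mean value of at least 5, the length slope alone and with replicate strata, limma array weights, and leaving out the 6 libraries whose median correlation with their own group was under 0.9.

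The procedure was tested on simulated data with 200 changed genes per comparison among 11461, taken from genes with a mean value of at least 5. Each gene was simulated independently, without the shared variation between libraries, of which the first component held 51.9% of the within-group variance in the real data. The shares below therefore need not hold for the real libraries. At a change of 1 on the log2 scale it recovered 70.1% of genes at 0 h in the rest phase and 68.7% in the active phase. At 2 it recovered 95.5% and 100%. For the interaction at 4 h it recovered 41.8% at 1, 70.1% at 1.5 and 87.9% at 2. Rhythms with an amplitude of 0.5 were recovered for 76.1% of genes in the rest arm and 82.1% in the active arm.

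Some counts are given in the report as a share of the 11461 genes. Exercise in the active phase at 0 h called 135 genes, 112 higher and 23 lower, and 108 genes were rhythmic in sham mice of the rest arm. At an unadjusted p under 0.05 the interaction had 114, 199, 456, 607, 103 and 77 genes at the hours in order and 107 jointly, and exercise in the active phase had 102 at 16 h and 96 at 20 h. By chance a share of 0.05 of genes would be expected on average at this threshold, which of these counts only that of the interaction at 12 h (5.30%) exceeded. Variation shared between libraries can move the share of a single contrast to either side, so a lower share does not show that no effect exists. The result of 1 gene is not reported here.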

Results

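Mice ran on a treadmill for 1 h, or stood on a stationary treadmill (sham), beginning in the early rest phase at ZT3 or in the early active phase at ZT15, where ZT0 is lights on in a cycle of 12 h of light and 12 h of darkness. Gastrocnemius, a calf muscle of mixed but mainly fast fibres, was taken directly after the treadmill (0 h) and then every 4 h up to 20 h. Sham mice of an arm are its sedentary controls, and each arm had its own. Phase, treatment and hour formed 24 groups. Of these, 18 held 6 libraries, 5 held 5 and 1 held 4, the exercised mice of the rest phase at 0 h. Values below are the deposited ones, reads per M (mega) of a scaled library size. Changes are log2 fold changes of value + 0.5 with their standard error (SE), and levels are means with their standard deviation (SD) over n libraries, 1 mouse each.

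Directly after exercise in the rest phase, muscle held more mRNA of immediate early genes than muscle of sham mice at the same clock time. The largest rise among named genes was in Ddit4, an inhibitor of mTORC1 signalling, at 2.86 ± 0.44 (n = 4 against 5), from 17.2 ± 13.7 (SD) in sham to 106.8 ± 11.5 in exercised mice. Btg2, an antiproliferative immediate early gene, rose by 2.55 ± 0.33 and the transcription factor gene Maff by 2.39 ± 0.31. Mt1, which encodes the metal-binding protein metallothionein 1, rose by 2.42 ± 0.37, from 8.30 ± 1.903 to 46.6 ± 10.5. The salt-inducible kinase gene Sik1 rose by 2.53 ± 0.49, and the stress-induced transcription factor gene Atf3 by 2.32 ± 0.50. Junb and Fosl2, which encode parts of the AP-1 transcription factor, rose by 2.27 ± 0.44 and 2.01 ± 0.35. Further rises were found for Depp1, a FoxO target, at 2.01 ± 0.45, and Csrnp1 at 1.97 ± 0.39. Myct1 fell by 1.20 ± 0.24 and Arsi fell by 1.18 ± 0.29.

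Over all measured genes 40 passed in the rest phase at 0 h, 38 higher and 2 lower after exercise. Of 21 measured immediate early genes 9 rose, and 15 rose when adjusted over the list alone; Zfp36, a regulator of mRNA decay, rose by 1.86 ± 0.35 and the nuclear receptor gene Nr4a1 by 1.43 ± 0.34. The list passed the camera test (adjusted p = 4.2e-16) and kept an adjusted p = 0.039 with an estimated correlation. Among 24 measured glucocorticoid targets 8 rose, and 18 when adjusted over the list alone (camera adjusted p = 6.4e-19; adjusted p = 0.0027 with an estimated correlation). Its members included Arrdc3 at 1.24 ± 0.17, Arrdc2 at 1.37 ± 0.30 and Trim63, a muscle ubiquitin ligase of protein breakdown, at 1.156 ± 0.22, and Mt1, Dusp1 and Per1 stand in this list as well as in other groups named here. Among 18 core clock genes Ciart rose by 1.47 ± 0.34, Per1 by 1.32 ± 0.29 and Nfil3 by 1.07 ± 0.21, with 7 when adjusted over the list alone (adjusted p = 0.37 with an estimated correlation, and 0.031 when the length slope was a covariate). Of 22 genes of FoxO signalling and protein breakdown 2 rose, Trim63 and Irs2 (1.95 ± 0.47), and 6 when adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). Nfkbia, an inhibitor of NF-kB, at 0.87 ± 0.21 was the riser among 12 measured genes of cytokines and inflammation, in which Metrnl stood at -0.84 and fell when adjusted over the list alone. Of 11 fast fibre markers none passed over all genes by limma, and 4 when adjusted over the list alone (adjusted p = 0.41 with an estimated correlation, and 0.031 when the length slope was a covariate).

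With adjusted p values from limma, Btg2 and Maff stood at 3.6e-08, Mt1 at 3.4e-06 and Ddit4 at 5.3e-06, and each of the 4 exercised libraries lay above all 5 sham libraries for these genes. At an unadjusted p under 0.05 there were 1717 genes. The transcript-length slope also moved with exercise in these libraries, being -0.01 ± 0.03 (SD) in exercised and -0.18 ± 0.06 in sham mice. The count was 3653 with only these 9 libraries in the fit, 3201 with array weights, 71 with the length slope and replicate strata, and 16, 22 and 24 without exercised replicate 2, exercised replicate 1 and sham replicate 1. The median size of the change over the 40 genes, which were chosen on these libraries, was 1.62 within replicates 1 and 2 and 1.06 within 5 and 6, while replicates 3 and 4 held no exercised library. Dusp1 lost its call under 2 alternatives and Ciart and Irs2 under 1. With 1 of the 9 libraries left out Dusp1 lost it in 7 fits, Irs2, Nfkbia and Arsi in 5, Nr4a1 in 4, Ciart and Per1 in 3, Atf3, Depp1 and Arrdc2 in 2, and Myct1 and Nfil3 in 1.

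In the active phase Junb had the largest rise among named genes, by 4.00 ± 0.37 (n = 6 against 6), from 4.68 ± 0.77 (SD) to 108.1 ± 70.6, and Fos by 3.205 ± 0.49, from 4.15 ± 3.51 to 44.04 ± 29.1. Btg2 rose by 3.44 ± 0.29 and the orphan nuclear receptor gene Nr4a3 by 3.04 ± 0.56. Maff, Sik1, Fosl2 and Mt1 rose by 2.79 ± 0.27, 2.72 ± 0.43, 2.60 ± 0.30 and 2.37 ± 0.32. Ciart, a repressor of the circadian clock, rose by 2.74 ± 0.29, from 1.01 ± 0.49 to 10.1 ± 4.73. Irs2, an adaptor of insulin signalling, rose by 2.31 ± 0.41. Among the falls were the zinc finger genes Zfp982 (-1.30 ± 0.29), Zfp979 (-1.08 ± 0.28), Zfp14 (-0.97 ± 0.24) and Zfp760 (-0.96 ± 0.25), and March1 (-1.18 ± 0.27). St8sia4, Olfml1 and the glutamate transporter gene Slc1a3 fell by 0.92 ± 0.17, 0.91 ± 0.24 and 0.88 ± 0.23, and the chemokine receptor genes Cxcr4 and Ccr2 fell by 0.87 ± 0.25 and 0.87 ± 0.24.

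At this hour 1.18% of genes passed, 23 of them lower and the others, 0.977% of genes, higher (0.349% had passed in the rest phase). Of the 21 immediate early genes 14 rose, and 17 when adjusted over the list alone (camera adjusted p = 9.3e-29; adjusted p = 0.0009 with an estimated correlation); Klf4 and Egr1 stood at 1.83 ± 0.25 and 1.83 ± 0.47. Core clock genes rose in 3 of 18 cases, Ciart, the repressor gene Cry2 (1.48 ± 0.28) and Nfil3 (0.74 ± 0.18), and in 6 when adjusted over the list alone (adjusted p = 0.37 with an estimated correlation, and 0.035 when the length slope was a covariate). Of 24 glucocorticoid targets Mt1, Dusp1 (1.17 ± 0.20) and Trim63 (0.94 ± 0.19) rose, and 10 when adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). Irs2 and Trim63 were the 2 risers among 22 genes of FoxO signalling and protein breakdown, with 6 when adjusted over the list alone (adjusted p = 0.47 with an estimated correlation). Of 24 genes of extracellular matrix and mechanical load 3 rose both ways, among them the matrix glycoprotein gene Thbs1 (1.61 ± 0.38) and Adamts1 (1.20 ± 0.33), with adjusted p = 0.84 with an estimated correlation. Among 19 measured genes of insulin and glucose handling Irs2 was the riser in both phases (adjusted p = 0.83 with an estimated correlation in each). The heat shock gene Hspa1b stood at 1.57 ± 0.47 (adjusted p = 0.070). It passed under 4 of 13 alternatives (adjusted p from 0.021 to 0.12 over all of them), and 2 of 22 heat shock and chaperone genes passed when adjusted over the list alone (adjusted p = 0.83 with an estimated correlation).

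The limma adjusted p was 4.2e-18 for Btg2, 2.7e-15 for Junb and 7.9e-15 for Maff, with all 6 exercised libraries above all 6 sham libraries for each. At an unadjusted p under 0.05 there were 2484 genes, and the length slope was -0.01 ± 0.19 (SD) in exercised and -0.16 ± 0.08 in sham mice. The count was 3484 with array weights, 231 with only these 12 libraries, 219 with the slow-fibre covariate, 216 with the length slope and replicate strata, 83 among genes with a mean value of at least 5, and 70, 89 and 311 without exercised replicate 1, sham replicate 1 and exercised replicate 4. Cxcr4 and Ccr2 each lost their call under 5 alternatives, Zfp760 under 2, and Slc1a3, Egr1 and Adamts1 under 1 each. With 1 of the 12 libraries left out Adamts1 lost it in 9 fits, Cxcr4 in 8, Ccr2 in 7, Egr1, Zfp979 and Olfml1 in 5, Slc1a3 and Zfp14 in 4, Zfp760 and Nfil3 in 2 and Thbs1 in 1. The median size of the change over the genes that passed, which were chosen on these libraries, was 1.39 within replicates 1 and 2, 0.64 within 3 and 4 and 1.05 within 5 and 6.

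**Figure D1:**
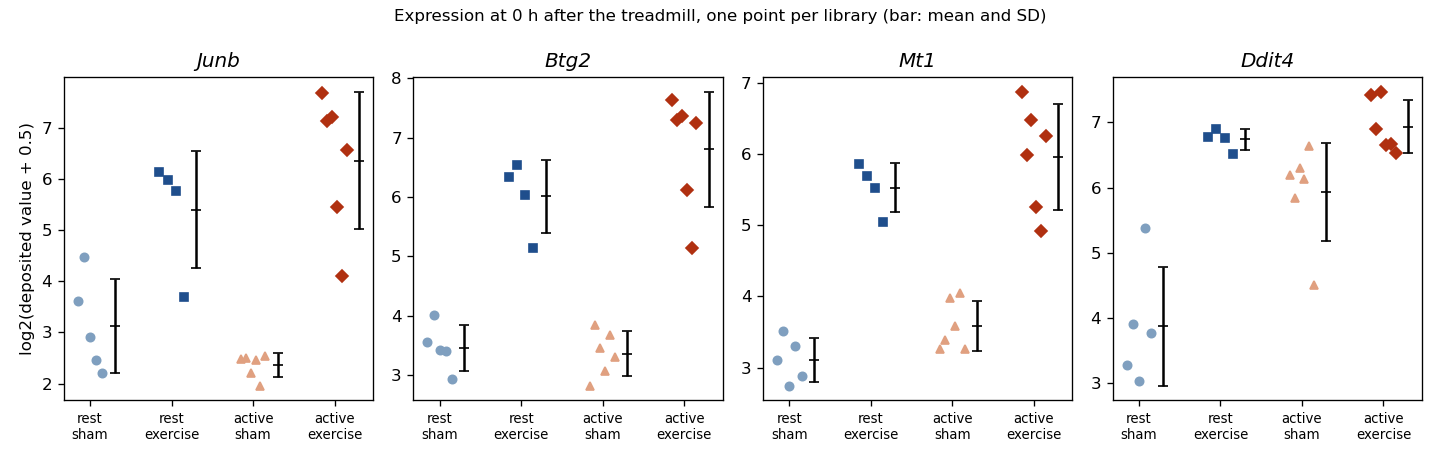
Expression of Junb, Btg2, Mt1 and Ddit4 at 0 h after the treadmill, as log2 of deposited value + 0.5 on the vertical axis of each panel, in sham and exercised mice of the rest and active phase. Points are libraries and bars the mean with its SD (n = 5, 4, 6 and 6 from left to right); all exercised libraries lie above all sham libraries of their phase for Btg2 and Mt1, while for Junb 1 exercised library of the rest phase lies within the sham range.

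Junb (ENSMUSG00000052837.6) lies on chromosome 8 of GRCm38 from 84974484 to 84978718 and Mt1 (ENSMUSG00000031765.8) on the same chromosome from 94179082 to 94180327. Btg2 (ENSMUSG00000020423.6) lies on chromosome 1 from 134075170 to 134079120, and Ddit4 (ENSMUSG00000020108.4) on chromosome 10 from 59949669 to 59951834. All 4 are annotated as protein-coding genes.

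The study's design asks whether the response depends on the phase in which exercise took place. The interaction, active minus rest, was 1.74 ± 0.57 for Junb, 2.11 ± 0.73 for Egr1 and 1.28 ± 0.41 for Ier2, of which Egr1 and Ier2 stood at -0.28 ± 0.55 and -0.28 ± 0.31 in the rest phase (adjusted p = 0.75 and 0.56). In exercised replicate 6 of the rest phase Junb stood apart at 3.70 on the log2 scale (nearest 5.76), and without this library its interaction was 1.17 ± 0.58. Conversely, the interaction was -1.86 ± 0.59 for Ddit4, -1.22 ± 0.39 for Arrdc2 and -0.81 ± 0.23 for Arrdc3. Sham levels of Ddit4 differed between the phases (17.2 ± 13.7 SD in the rest and 66.5 ± 25.8 in the active phase), and exercised levels were 106.8 ± 11.5 and 126.4 ± 37.6. These 3 immediate early genes and 3 glucocorticoid targets passed when adjusted over the list alone, and none passed over all genes (adjusted p = 1.00 each). The immediate early list differed by camera (median 0.28, adjusted p = 2.0e-06; adjusted p = 0.88 with an estimated correlation), as did the glucocorticoid targets (median -0.35, adjusted p = 1.2e-10; adjusted p = 0.14 with an estimated correlation). By limma 0 genes passed the interaction at any hour or over the 6 hours together. The share of genes at an unadjusted p under 0.05 was lowest at 20 h (77 genes), stood at 0.995% at 0 h, 1.74% at 4 h, 3.98% at 8 h, 5.30% at 12 h and 0.899% at 16 h, and was 0.934% jointly. By chance a share of 0.05 would be expected on average, which only the value at 12 h exceeded. Variation shared between libraries can move the share of a single contrast to either side. A share below 0.05 therefore does not show that the phase has no effect. DESeq2 called 4 at 0 h and 4 jointly, and edgeR 0 throughout. With array weights 1697 genes passed at 8 h, 19 at 12 h, 4163 at 20 h and 4895 jointly. With phase labels exchanged among the same libraries, limma without weights called up to 7, 3836 and 3878 genes at these hours and 1030 jointly.

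At 0 h the log2 fold changes of the phases, which share no library, correlated across all genes (Pearson r = 0.85, Spearman rho = 0.86). Genes are not independent replicates, and no p was computed. With the length slope as a covariate r was 0.53. Among called genes 27 rose in both phases, against 0.371 expected if the calls were independent, and all 40 genes of the rest phase had the same sign in the active phase. The calls are not independent, because both phases share 1 estimate of the spread of each gene. The length slope was also higher after exercise in both phases, so this overlap does not measure a shared response to exercise alone. Pearson r was 0.62 at 4 h, 0.43 at 8 h, -0.27 at 12 h, -0.07 at 16 h and 0.40 at 20 h. These were 0.143, 0.161, 0.0167, 0.286 and 0.130 with the length slope as a covariate. Without replicate 5 r was 0.0377 at 4 h, and without replicate 1 it was 0.0736 at 8 h. The sign turned at 12 h (0.243 without replicate 1), at 16 h (0.138 and 0.00857 without replicates 2 and 4) and at 20 h (-0.291 without replicate 4).

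Mt1 passed at several later hours, though not at 4 or 8 h in the active phase. After exercise in the rest phase it was higher by 1.66 ± 0.32 at 4 h (n = 6 against 6), 1.79 ± 0.33 at 8 h (6 against 5) and 1.38 ± 0.32 at 12 h (6 against 6), and after exercise in the active phase by 1.82 ± 0.32 at 12 h (6 against 6), from 6.51 ± 2.23 (SD) to 25.5 ± 11.6. Atf3 was higher by 2.02 ± 0.43 at 4 h and 2.01 ± 0.43 at 12 h in the rest phase. At 12 h in the rest phase Csrp3, a muscle LIM protein gene responsive to mechanical load, rose by 1.92 ± 0.37, from 102.3 ± 49.8 to 354 ± 84.5. At that hour Lmcd1 rose by 0.94 ± 0.20, Egln3, a prolyl hydroxylase that acts on HIF proteins, rose by 0.76 ± 0.17, and Pqlc3 fell by 0.96 ± 0.20. In the active phase at 4 h the elongation factor gene Ell2 rose by 1.03 ± 0.20 and Impact, an inhibitor of the kinase GCN2, by 0.87 ± 0.16 (n = 5 against 6).

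Ppargc1a, the coactivator of mitochondrial biogenesis, did not pass at any hour with limma over all genes. At 8 h in the active phase it passed under 9 of 14 alternatives, DESeq2 and edgeR among them. It stood at 0.97 ± 0.28 (adjusted p = 0.81) at 4 h in the rest phase and, in the active phase, at 0.78 ± 0.29 (adjusted p = 0.53) at 4 h and 1.39 ± 0.29 (adjusted p = 0.055) at 8 h, when it was 14.9 ± 1.47 (SD) in sham and 42.2 ± 17.3 in exercised mice. With the length slope as a covariate it passed at these hours, at 1.19, 1.05 and 0.91, and its adjusted p ran over the alternatives from 1.8e-06 to 0.99, from 0.00021 to 0.54 and from 7.2e-08 to 0.17. Of 18 regulators of mitochondrial biogenesis 1 passed when adjusted over the list alone at 4 h in the rest phase and 1 at 8 h in the active phase (adjusted p = 0.93 and 0.83 with an estimated correlation).

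In all, 2, 1 and 6 genes passed at 4, 8 and 12 h in the rest phase, and 2, 0 and 1 in the active phase. At 16 and 20 h none passed by limma in either phase. At an unadjusted p under 0.05 there were 193 and 205 genes (1.68% and 1.79%) in the rest phase and 0.890% and 0.838% of genes in the active phase. These shares lie below the 0.05 expected by chance on average, while the active phase at 8 h lay above it (2805 genes, 24.5%). Because libraries share variation, neither side of 0.05 shows the absence or presence of an effect. DESeq2 called 0 and 3 genes in the rest phase at 16 and 20 h, 2 in the active phase at 8 h, and 4 at each of 16 and 20 h, while edgeR called 0, 1, 2, 0 and 0. Csrp3 and Ankrd2, a second load-responsive gene, stood at 1.43 ± 0.37 and 1.03 ± 0.24 at 20 h in the rest phase (adjusted p = 0.47 and 0.13). Csrp3 passed there under 3 of 14 alternatives (adjusted p from 1.6e-06 to 0.98 over all of them) and Ankrd2 under 4 (3.0e-07 to 0.98). Without exercised replicate 6 both passed and the count became 5, and in the active phase at 8 h the count became 2113 without exercised replicate 6. Array weights gave 12, 4, 0, 0 and 6212 genes from 4 to 20 h in the rest phase and 3117, 5067, 525, 2029 and 0 in the active phase. With treatment labels exchanged among the same libraries, limma without weights called up to 6073 genes at 20 h in the rest phase. A count of that size there need not reflect exercise. At 8 h in the active phase the highest such count was 0, and exchanged labels were not fitted with weights. At 20 h in the rest phase the length slope gave 4 genes, and 7 with replicate strata. Without 1 library the count at 4 h in the rest phase was 0 (exercised replicate 1 or 2, sham replicate 3 or 4) or 1 (exercised replicate 4, 5 or 6, sham replicate 1, 2 or 5), and at 8 h 0 (sham replicate 5 or 6). At 12 h in the rest phase it was 0 (exercised replicate 2 or 5, sham replicate 3), 1 (sham replicate 2 or 6), 2 (sham replicate 4) or 3 (exercised or sham replicate 1), and at 4 h in the active phase 0 (exercised replicate 1), 1 (sham replicate 2 or 4), 5 (sham replicate 6) or 6 (exercised replicate 4 or 5). At 12 h in the rest phase Mt1 and Pqlc3 lost their call under 4 alternatives, Atf3, Lmcd1 and Egln3 under 2 and Csrp3 under 1, and at 4 h Mt1 under 2. With 1 of the 12 libraries left out at 12 h Mt1 lost its call in 11 fits, Lmcd1 in 10, Egln3 in 8, Atf3 in 7, Pqlc3 in 5 and Csrp3 in 4. Mt1 lost it in 4 fits at 4 h and 2 at 8 h. In the active phase Ell2, Impact and, at 12 h, Mt1 lost it under 1 alternative. Ell2 lost it in 3 fits and Impact in 1 with 1 library left out. Atf3 at 4 h in the rest phase lost its call under 9 of 14 alternatives and in 10 of 12 fits with 1 library left out, and passed barely (adjusted p = 0.0497), and of its 6 exercised libraries 1 lay above all sham libraries.

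Among 28 gene lists with 336 tests of exercise, 60 passed camera with the preset correlation and 3 with an estimated one, the immediate early genes at 0 h in each phase and the glucocorticoid targets at 0 h in the rest phase. At 8 h in the rest phase 24 of 25 genes of fatty acid oxidation were positive (median 0.21, camera adjusted p = 7.8e-07; adjusted p = 0.37 with an estimated correlation), though none passed alone. Neither at 0 h in the rest phase nor in the active phase did any member pass over all genes by limma in the lists of mitochondrial biogenesis (18 measured), glycolysis (25), HIF1 targets (22), fatty acid oxidation (25), branched-chain amino acid breakdown (21), heat shock and chaperones (22), the integrated stress response (12), endoplasmic reticulum chaperones (18), lipid and sterol synthesis (21) and oxidative phosphorylation (30). The same held for markers of slow fibres (10), fast fibres (11), adipocytes (8), endothelium (10), macrophages (9), neutrophils (1), lymphocytes (2), red blood cells (5), satellite cells (5), Schwann cells (7) and fibroblasts (10).

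Clock genes cycled in sham muscle. Arntl (Bmal1), the transcriptional activator of the clock, peaked at ZT 22.2 ± 0.505 h (SE) in the rest arm and ZT 0.0571 ± 0.402 h in the active arm, with amplitudes of 0.99 ± 0.13 and 1.39 ± 0.14 on the log2 scale (n = 34 and 35 libraries). Dbp, an output gene of the clock, peaked at ZT 9.51 and ZT 10.8 with amplitudes of 0.87 ± 0.10 and 1.36 ± 0.10. The repressor gene Per2 peaked at ZT 12.5 and ZT 13.9, with amplitudes of 1.17 ± 0.11 and 1.46 ± 0.13, and Nr1d1 (Rev-erb alpha) at ZT 4.01 and ZT 6.46, with 0.84 ± 0.18 and 1.54 ± 0.15. Outside the clock list the strongest rhythms included Spon2 with 1.04 ± 0.16, Mid1ip1 with 0.74 ± 0.09 and Rflnb with 0.52 ± 0.07 in the rest arm, and Wsb1 with 0.79 ± 0.07 in the active arm.

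Within each arm a clock time is also a fixed hour after the stationary treadmill, so time of day and time since handling are confounded in each series. Ciart, Per1 and Nr1d1 were among the genes that differed between the sham arms. Of 18 clock genes 9 were rhythmic in sham mice of the rest arm and 13 in those of the active arm, and of all genes 0.942% and 2.48% (284), 62 of them in both against 2.68 expected if independent. The arms share 1 estimate of the spread of each gene, so their calls are not independent. Among those 62 genes 50 peaked within 2 h of each other in the arms. The smallest adjusted p was 5.5e-11 (Per2) in the rest arm and 7.7e-22 (Dbp) in the active arm. The count for the active arm was 795 with an F test among 6 clock times, and with the length slope as a covariate 382 and 787 genes passed in the rest and active arm. After exercise in the rest phase the amplitude was 0.56 ± 0.11 for Dbp and 0.73 ± 0.12 for Per2, and the median over 18 clock genes was 0.30 against 0.42 in sham mice. After exercise in the active phase it was 0.63 against 0.55. By limma 0 genes changed their rhythm with exercise in either arm, with 190 and 158 (1.66% and 1.38%) at an unadjusted p under 0.05. This is below the share of 0.05 expected by chance on average, which does not show that the rhythms stayed the same. DESeq2 called 0 and 20 genes and edgeR 0 and 14, and array weights gave 858 in the rest arm.

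**Figure D2:**
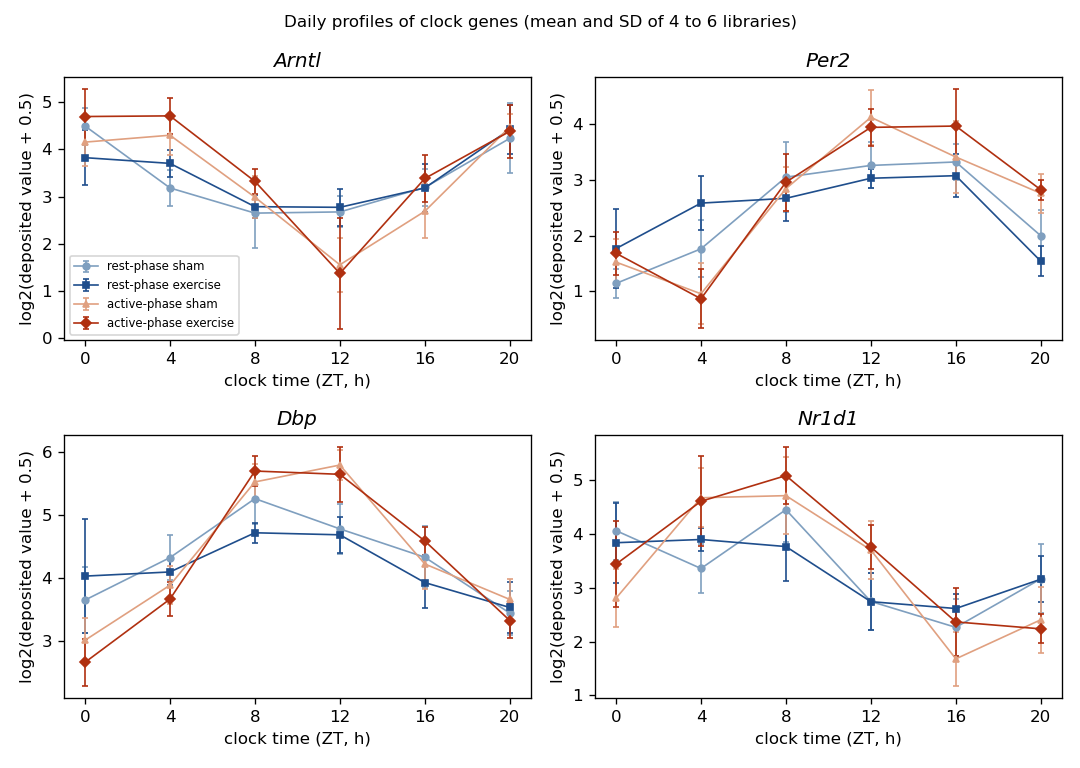
Daily profiles of Arntl, Per2, Dbp and Nr1d1, with clock time (ZT, h) on the horizontal and log2 of deposited value + 0.5 on the vertical axis, for sham and exercised mice of the rest and active phase. Points and bars are the mean and SD of 4 to 6 libraries; in sham mice Per2 peaked at ZT 12.5 in the rest and ZT 13.9 in the active arm.

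Sham mice of the arms, taken at the same clock times but at different hours after the stationary treadmill, also differed. Ddit4 was lower in the active than in the rest arm at ZT4, by -1.95 ± 0.40, when the rest arm had just left the treadmill, and higher by 3.79 ± 0.38 at ZT16, when the active arm had. Arrdc2 stood at -1.55 ± 0.27 and 2.05 ± 0.26, the leucine zipper gene Tsc22d3 (GILZ), a glucocorticoid target, at -0.97 ± 0.17 and 0.89 ± 0.16, and the kinase gene Sgk1 at -0.76 ± 0.16 and 0.62 ± 0.15. The mitochondrial carrier gene Slc25a25, chosen after its values were seen, stood at -2.64 ± 0.42 and 2.11 ± 0.40. Ucp3, which encodes a mitochondrial uncoupling protein of muscle, was lower in the active arm by -1.54 ± 0.28 at ZT8 and higher by 1.58 ± 0.26 at ZT20, and Pdk4, an inhibitor of glucose oxidation, was higher by 2.02 ± 0.36 at ZT20.

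By the limma F test 88 genes differed between the sham arms. In the arm just off the treadmill 50 of them were higher at both ZT4 and ZT16, and 32 were lower at both. At single clock times 19 genes passed at ZT4, 12 of them higher in the rest arm, and 81 at ZT16, 61 of them higher in the active arm, with 2 at ZT8, 3 at ZT12, 2 at ZT20 and 0 at ZT0 (1253 at an unadjusted p under 0.05; not run with another tool by clock time). The Ddit4 adjusted p was 6.1e-13 over the clock times. Groups had 5 or 6 libraries. The length slope was -0.18 ± 0.06 (SD) in the rest and 0.04 ± 0.18 in the active arm at ZT4, and 0.01 ± 0.18 and -0.16 ± 0.08 at ZT16. The F test gave 370 genes with DESeq2, 240 with replicate strata, 186 with the replicate number as a term and 6543 with array weights. Of the 88 genes, 47 also passed with the length slope as a covariate, which is an overlap and not the full count under that setting.

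**Figure D3:**
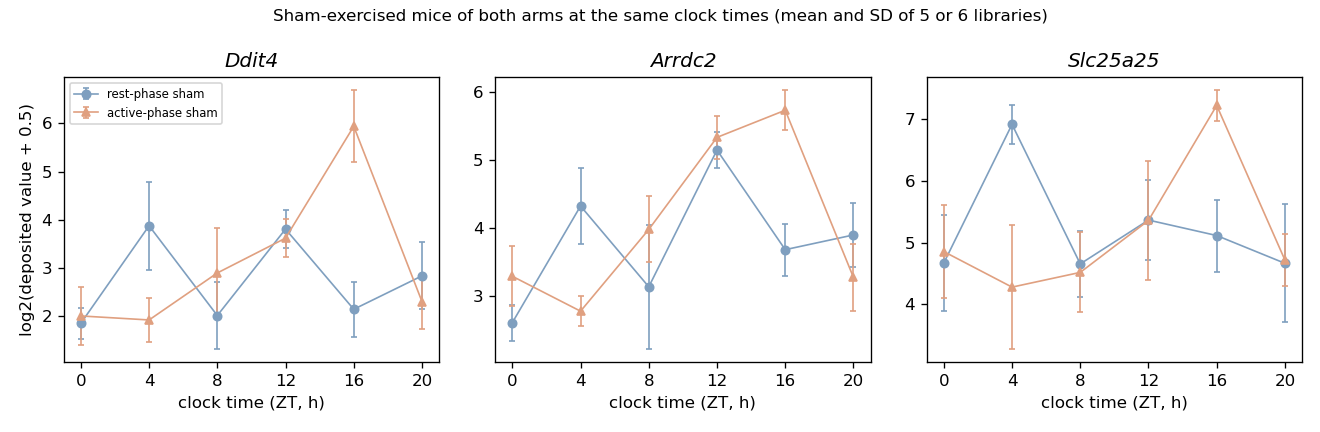
Expression of Ddit4, Arrdc2 and Slc25a25 in sham mice of the rest and active arm by clock time (ZT, h), as log2 of deposited value + 0.5, with the mean and SD of 5 or 6 libraries. The rest arm stood on the treadmill just before ZT4 and the active arm just before ZT16, where each arm lies above the other.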

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

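The tests of the causes of the sham arm difference and of the interaction of the immediate early list were chosen only after the results were seen.

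When the 9 rest-phase libraries at 0 h were fitted alone, 3653 genes passed in place of 40. The predicted log2 fold change from the transcript-length slope of each library correlated with the observed one across all measured genes (r = 0.853). The one from sequencing depth did so nearly as well (r = 0.819). The coefficients of the genes were fitted on the other groups. The length slope was, however, computed from the same expression values, so that a positive r for it was partly given. The predictions correlated with each other (r = 0.917), and genes are not independent replicates. After the slope term the share of the 3653 genes with the same sign in the active phase was 0.777, between the bounds set for and against exercise itself, so exercise and the library differences cannot be told apart for them. The median residual SD was 0.255 in this fit against 0.408 in the shared one while the fold changes were the same, so the additional calls go with a smaller spread, and a candidate explanation for their fold changes is a difference in length bias between the groups (median size 0.62, and 0.20 after the slope prediction). Of the 40 genes, 37 also passed with the slope as a covariate.

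Sham mice of the arms differed at equal clock times. Across the 88 genes, which were chosen on these libraries, the differences at ZT4 and ZT16 correlated negatively. The r was -0.837, with 82 of 88 of opposite sign, and -0.745 over all genes. This argues only against a difference of the same sign and size at both clock times. Recent handling on the stationary treadmill would give a negative r. So would a differing daily rhythm in the arms that turns sign between these clock times, so the test does not single out handling. With the length slope as a covariate the correlation was -0.778, with 78 of 88 opposite and 47 of 88 still past the threshold. A linear slope term thus did not remove the pattern. The slope itself also turned sign between the arms, at -0.18 in the rest and 0.04 in the active arm at ZT4 and 0.01 and -0.16 at ZT16. It was computed from the same expression values, so differences in length bias between the libraries are not excluded. The hours since the treadmill and any other arm-specific handling could not be separated, and recent handling may account for the difference only as a hypothesis found on these data.

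More genes passed at 0 h in the active than in the rest phase. Draws of active-phase libraries of the size of the rest phase gave a median of 87.5 genes over 58 draws (34 to 2575), 15 of them at most 60 and 4 at most 40, so that the fewer libraries may account for part of the difference. The immediate early list did not pass the interaction with an estimated correlation (adjusted p = 0.876). The draws were all of 1 size and span both counts, so which libraries were drawn also moved the count. The phase, the number of libraries and differences between single libraries cannot be told apart as the reason.

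Results were compared with 100 splits of the same libraries, the real one counted among them. Under 5 gave as many genes for the rest phase at 0 h (1 split, 40 genes, highest other 22), 8 h (3, 1 and 1) and 12 h (1, 6 and 4). The same held for the active phase at 0 h (2, 1.18% of genes and 173 genes) and 4 h (4, 2 and 2536) and for the sham arms (1, 88 and 3). It also held for rhythm in the rest arm (1, 0.942% of genes and 1 gene) and the active arm (2, 284 and 3401). The cut of 5 was not adjusted for the number of results, so it does not exclude chance. The counts at 8 and 12 h in the rest phase and 4 h in the active phase also fell to 0 in some fits with 1 library left out. At 4 h in the rest phase 5 splits gave as many (2 genes, highest other 100), and at 12 h in the active phase 5 did (1 and 5091). Where 0 genes had passed by limma, 100 of 100 splits gave as many, which was fixed in advance. The unadjusted and other-tool counts of those stand in the report, and their highest other splits were 1 and 6073 for the rest phase at 16 and 20 h, 0, 4064 and 3960 for the active phase at 8, 16 and 20 h, 19, 3114, 7, 3836, 4049 and 3878 for the interaction from 0 to 20 h and 1030 jointly, and 172 and 4151 for the change of rhythm in the rest and active arm. Splits that called far more genes than the real one may reflect a structure of the samples, but no cause was tested and they were not examined split by split.

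By Dixon's test a library stood apart in 5 of 72 groups for library measures and in 5 of 88 groups for named genes, where chance gives about 1 in 20. The length slope of replicate 4 of the exercised rest phase at 4 h was 0.227 (nearest -0.05). Recovered reads, in M (mega), were 26.1 in rest sedentary 4 h replicate 5 (nearest 13.1), 17.6 in active exercised 4 h replicate 5 (11.1), 20.4 in active exercised 8 h replicate 1 (12.3) and 18.6 in active sedentary 20 h replicate 4 (11.7). On the log2 scale Junb was 3.70 (nearest 5.76) and Csrnp1 2.04 (2.87) in rest exercised 0 h replicate 6, Atf3 5.63 (3.08) in rest sedentary 4 h replicate 6, Pqlc3 0.14 (1.29) in rest exercised 12 h replicate 2 and Ell2 5.08 (5.84) in active exercised 4 h replicate 2.

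Lists differed between the phases by camera with the preset correlation, and none with an estimated one (adjusted p = 0.144 for glucocorticoid targets at 0 h and 0.876 to 0.887 for the others). Median interactions at 0 h were 0.28 for immediate early genes (adjusted p = 2.0e-06), -0.35 for glucocorticoid targets (1.2e-10) and 0.46 for slow fibre markers (0.010). At 4 h they were -0.14 for heat shock genes (0.034), -0.30 for extracellular matrix genes (0.013), -0.43 for endothelium (0.010), -0.32 for macrophages (0.044) and -0.48 for Schwann cells (0.012). At 8 h they were -0.40 for oxidative phosphorylation (0.048) and 0.39 for insulin and glucose handling (0.046), and at 12 h -0.40 for oxidative phosphorylation (0.048) and -0.27 for fibroblasts (0.037). At 16 h they were 0.50 for extracellular matrix (2.0e-06), -0.33 for oxidative phosphorylation (0.012) and 0.22 for insulin and glucose handling (0.033), and at 20 h -0.12 for fatty acid oxidation (0.018), -0.56 for slow fibres (1.6e-05) and -0.34 for adipocytes (0.013).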

How the results depend on the processing

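The settings edgeR, pseudocounts of 0.1 and 2 for the counts, a mean value of at least 5, the length slope with and without replicate strata, array weights and the omission of 6 libraries were chosen after the results were seen. Counts depended on the settings, which differ in more than how the spread was estimated. Of 14 settings, 12 moved the count by more than 1.5 times at 4 h in the rest phase, 8 at 4 h and 9 at 8 h in the active phase, and at most 6 at the other hours of either phase. The submitters' own filter could not be undone from the deposited values, so no value without a filter is given here. A stricter one is among the settings below. For the genes named with an exercise effect or an interaction no direction reversed; the directions at single clock times and the peaks of rhythms were not followed over the settings. Over all named results, with p values alone for the sham arms and rhythms, and over other settings 1433 were the same, 38 stronger and 50 weaker, with 1 library left out 880, 14 and 163. Of the 40 genes of the rest phase at 0 h, edgeR called 37, DESeq2 39 and array weights 40.

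With a fit limited to the libraries of the contrast, exercise in the rest phase called 3653 genes at 0 h, 0 at 4 h and 3 at 8 h, and in the active phase 231 at 0 h, 0 at 4 h and 0 at 12 h. With array weights it called 3201, 12, 4, 0 and 6212 at 0, 4, 8, 12 and 20 h in the rest phase and 3484, 3117, 5067, 525 and 2029 at 0, 4, 8, 12 and 16 h in the active phase. The interaction had 1697, 19 and 4163 at 8, 12 and 20 h and 4895 jointly, the sham arms 6543, rhythm 3846 and 1392 in the rest and active arm, and its change 858 and 1.

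With the length slope exercise called 11, 15 and 4 at 4, 12 and 20 h in the rest phase and 8, 1 and 2 at 4, 8 and 12 h in the active phase, rhythm 382 and 787, and its change 2 in the active arm. With the length slope and replicate strata it called 71, 13, 18 and 7 at 0, 4, 12 and 20 h in the rest phase and 216, 5, 1, 6 and 1 at 0, 4, 8, 12 and 16 h in the active phase, rhythm 498 and 917, and its change 2 in the active arm.

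DESeq2 called 5, 2 and 3 at 4, 8 and 20 h in the rest phase, 11, 2, 4 and 4 at 4, 8, 16 and 20 h in the active phase, 4 for the interaction at 0 h and 4 jointly, 370 for the sham arms and 20 for the change of rhythm in the active arm. EdgeR called 0 and 1 at 4 and 20 h in the rest phase, 10 and 2 at 4 and 8 h in the active phase, and 14 for that change. Pseudocount 2 gave 1 at 4 h in the rest phase, 5 and 1 at 4 and 8 h in the active phase and 1 for that change. Without the 6 libraries of low correlation there were 1 and 5 at 4 and 20 h in the rest phase and 5, 1 and 1 at 4, 8 and 16 h in the active phase. The slow-fibre covariate gave 1 at 4 h in the rest phase and 219 and 1 at 0 and 8 h in the active phase, and a mean value of at least 5 gave 83 and 1 there. RLE size factors, replicate strata and pseudocount 0.1 gave 1 each at 4 h in the rest phase, and replicate strata 240 for the sham arms. The F test among 6 clock times gave 795 for rhythm in the active arm. Of the 336 list tests of exercise, 60 by camera became 3 with an estimated correlation, 10 with fry and 6 with the slope and an estimated correlation, and the 18 of the interaction became 0, 0 and 0. With pseudocount 2 the median amplitude of the clock genes over the 4 series was 0.399 in place of 0.458.

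The correlation of the phases across genes was 0.530 at 0 h, 0.017 at 12 h and 0.286 at 16 h with the length slope, 0.540, 0.030 and 0.271 with the slope and replicate strata, 0.183 at 16 h with the slow-fibre covariate, and 0.035 at 16 h and -0.216 at 20 h with array weights. Leaving out 1 replicate number gave 0.758 to 0.852 at 0 h, 0.038 to 0.687 at 4 h, 0.0736 to 0.578 at 8 h, -0.384 to 0.243 at 12 h, -0.421 to 0.138 at 16 h (0.00857 without replicate 4) and -0.291 to 0.687 at 20 h.

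With 1 library left out the count for the rest phase ran from 16 to 42 at 0 h, 0 to 2 at 4 h, 0 to 1 at 8 h, 0 to 7 at 12 h and 0 to 5 at 20 h, and for the active phase from 70 to 311 at 0 h, 0 to 6 at 4 h and 0 to 2113 at 8 h; the libraries are named in the report, with active exercised replicate 2 at 8 h giving 1. The replicate numbers were not taken to pair the samples, because in each contrast at least 1 correlation between libraries of the same number was under 0.1. With the number as a replicate block 38 genes passed at 0 h in the rest phase and 186 for the sham arms, and exercised libraries correlated most with the sham library of their own number in 2 of 4 cases in the rest phase (mean r = 0.07) and 1 of 6 in the active phase (mean r = 0.16) at 0 h. The highest mean was 0.30 at 20 h in the rest phase (lowest -0.46) and the lowest mean -0.35 at 16 h in the active phase.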

Other observations

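The test of glucocorticoid targets in sham mice was chosen after the result was seen. In the active phase at 8 h after exercise, when the length slope was 0.12 ± 0.21 (SD, n = 5) in exercised and -0.08 ± 0.09 (n = 6) in sham mice, none passed over all genes by limma (2805 at an unadjusted p under 0.05; 2 by edgeR and 2 by DESeq2), but members of fixed lists passed when adjusted over the list alone. Pdk4, an inhibitor of glucose oxidation, stood at 1.34 ± 0.37, Mt1 at 1.22 ± 0.33, and the endothelial genes Kdr, which encodes VEGF receptor 2, and Cdh5, which encodes VE-cadherin, at 1.24 ± 0.44 and 1.35 ± 0.49 (adjusted p = 0.20 each over all genes). Over the alternatives Pdk4 ran from 0.81 to 1.66 (adjusted p from 1.4e-05 to 0.9998) and Mt1 from 1.10 to 1.39 (9.7e-05 to 0.86). Both passed with array weights and in 1 fit with 1 library left out. With the length slope as a covariate Kdr stood at 0.49 and Cdh5 at 0.50 (adjusted p = 1.00 each; over the alternatives 0.00017 to 1.00 for Kdr and 0.00011 to 1.00 for Cdh5), and without exercised replicate 6 both passed, at 1.53 and 1.75 (adjusted p = 0.047 each). Of 10 endothelial markers 6 passed over the list alone (camera adjusted p = 0.019; adjusted p = 0.83 with an estimated correlation), and of 24 glucocorticoid targets 6 did (camera adjusted p = 0.00012; adjusted p = 0.55 with an estimated correlation). The 8 adipocyte markers had a median of -0.75 (camera adjusted p = 0.017; adjusted p = 0.83 with an estimated correlation).

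At 8 h in the rest phase 22 of 24 glucocorticoid targets were positive, and 3 passed over the list alone (camera adjusted p = 1.4e-07; adjusted p = 0.32 with an estimated correlation). At 12 h in the active phase macrophage markers had a median of -0.42 (camera adjusted p = 1.1e-05) and fibroblast markers of -0.33 (7.8e-07), each with adjusted p = 0.37 with an estimated correlation. At 16 h extracellular matrix genes were lower in the rest phase (camera adjusted p = 0.00012) and higher in the active phase (0.012), with adjusted p = 0.83 with an estimated correlation for both. Fos stood at 1.72 ± 0.57 at 0 h in the rest phase (adjusted p = 0.29), and passed when the 9 libraries were fitted alone (adjusted p = 0.048) and with array weights (0.00054), with a range of 0.00054 to 0.68 over the alternatives.

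Glucocorticoid targets were compared between sham mice just off the stationary treadmill and sham mice of the other arm at the same clock time. At ZT16, 18 of 24 were higher in the former and 9 passed (median 0.67; adjusted p = 1.3e-13 with the preset and 0.0142 with an estimated correlation), and at ZT4, 13 of 24 were higher and 4 passed (median 0.14; adjusted p = 0.046 with the preset and 0.763 with an estimated correlation). In the same comparison slow fibre markers had medians of 0.51 at ZT16 and 0.74 at ZT4, 25 and 27 of 30 genes of oxidative phosphorylation and 5 and 4 of 24 of extracellular matrix were higher (adjusted p = 0.763 each with an estimated correlation, except 0.950 for extracellular matrix at ZT16; with the preset one 0.086 and 0.054 for slow fibres, 0.0080 and 0.0013 for oxidative phosphorylation and 0.35 and 0.0035 for extracellular matrix, at ZT16 and ZT4), and the length slope was lower in the mice just off the treadmill (-0.16 ± 0.08 against 0.01 ± 0.18, SD, at ZT16 and -0.18 ± 0.06 against 0.04 ± 0.18 at ZT4). Recent handling may raise these genes, as a hypothesis that the ZT4 value (adjusted p = 0.763) leaves open.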
